A study of Mus musculus with 9 samples.

How the data were processed

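Gene expression was measured by RNA sequencing of tibialis anterior muscle from 9 mice aged 4 to 6 months. The control group held 5 mice with a floxed Dmd allele, and the mKO group held 4 mice in which dystrophin was removed within the myofiber. Both genotype labels name the floxed allele, and only the mKO label adds HSA mKO. Anything else that came with this addition cannot be told apart from loss of dystrophin. Each library came from 1 mouse, so the replicate is the mouse. The series text gives 5 mice per group, and 1 more mKO mouse was not analysed here. Groups were taken from the sample labels, and the labels give no batch or date. Replicate numbers only name the mice and pair none of them. Control mice 1 and 2 carry title numbers in another range than control mice 3, 4 and 5, with no reason given. The title numbers of the mKO mice lie in a range apart from all controls, so the numbering follows the groups, also with no reason given.

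The authors deposited whole-number counts of reads per Ensembl gene. Per the submitters' processing notes, the tools were bcl2fastq, Trim Galore 0.6.10, STAR 2.7.10b and HTSeq 2.0.2, and the genome build was GRCm39. Per the series' design text, RNA with an integrity value above a set limit entered library construction, messenger RNA was isolated, first strands were primed with random hexamers, and low-quality reads were removed. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes may have been shared between them. The deposited counts had not been normalised, and libraries were not pooled. The table held 57010 gene identifiers and 5 rows of unassigned reads. These 5 rows stayed out of library sizes and tests. They made up 24.9% to 38.4% of all reads in the table in control libraries and 17.8% to 19.5% in mKO libraries. Symbols were found for 52029 identifiers in a table of gene names, and 4981 were kept under their identifier. The reference annotation at hand was of build GRCm38, so it was used for names and transcript sequences and no coordinates are given. HTSeq in its usual setting leaves out reads that match more than 1 place, so genes with near-identical copies are uncertain.

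Total gene counts ran from 14477673 to 32001371 per library. No libraries of a group agreed within sampling noise: the lowest chi-square per degree of freedom between libraries of a group was 16.1, over genes with at least 10 counts.

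Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default settings, which left 14403 genes, of which 14173 had a symbol. Libraries were scaled by TMM. The 2 groups were compared with the quasi-likelihood F-test, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05. A second edgeR test (glmTreat) asked for changes above 1.5-fold. Standard errors of log2 fold changes were derived from the F statistic. CPM values are counts scaled to a common library size by TMM. Log2 changes are mKO minus control throughout.

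Before the data were examined, 41 gene lists were fixed, together with the tests, the alternatives and the rule for named genes. A list was tested where at least 4 members passed the filter, which held for 39 lists. The lists were tested with camera in limma 3.58.1 against all other genes, with a preset inter-gene correlation of 0.01, and again with a correlation estimated per list. A list score was the mean log2 CPM of its members in a library, with a prior count of 2. Scores were compared between groups by a two-sided exact permutation test over all 126 assignments of the 9 libraries, whose smallest p is 0.00794, and adjusted over the 39 lists. Some lists share members, such as the C1q genes of the macrophage and complement lists. Within each list, calls were also counted after adjustment over the list alone.

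The rule for named genes took Dmd and Utrn in every case. It took the 10 largest rises and the 10 largest falls among called genes with a mean of at least 1 CPM, a symbol that is not a Gm number, Rik or pseudogene name, and no overlap between groups. From each list described it took up to 4 members with the smallest adjusted p. Lists described were those past the camera threshold, the lists of the dystrophin-associated complex and of the regenerating myofiber, and lists of other cell types past either list test. A gene that the rule takes is not reported here. Genes named outside this rule are marked as chosen after their values were seen.

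The steps were tested on simulated counts with the means and library sizes of this comparison. Of the simulated genes changed 1.5-fold, 35.3% of 68 were called, against 81.8% of 66 changed 2-fold and 100% of 66 changed 4-fold, in a step of 14173 genes. Of 151 calls, 7 were false, and no gene was called when nothing had been changed. Both list tests found 12 of 12 shifted lists and called 0 of 30 unshifted ones. The simulated genes varied independently, while the median estimated correlation within the real lists was 0.23. The simulation therefore does not show how often camera calls correlated lists falsely.

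Alternatives were DESeq2 size factors, upper-quartile scaling, library size alone, other low-count filters, the DESeq2 1.42.0 Wald test, limma-voom with and without quality weights, robust edgeR, each library left out in turn, controls 1 and 2 left out, and mitochondrial genes left out. For lists they also included fry, other prior counts and the median over members. Alternatives chosen after the data were seen left out controls 2, 3 and 4, used these as the only controls, left out an abundant unnamed feature together with Lars2, or left mitochondrial genes with a nuclear copy out of their list. Nuclear copies of mitochondrial genes were sought with BLAST 2.17.0 among the transcripts of the reference annotation. A copy was counted at an identity of at least 99% over at least 90% of the length.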

Results

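RNA sequencing of tibialis anterior muscle, a fast hindlimb muscle, compared 4 mKO mice with 5 control mice to find the molecular changes that go with loss of dystrophin in the myofiber. Total gene counts were 21070923, 31758463, 28255606, 22382726 and 14477673 in controls 1 to 5 and 25018233, 24831063, 29120617 and 32001371 in mKO 1 to 4. Expression is given as CPM, a gene's count scaled to a common library size after TMM. Values are means ± SD over the 5 control and 4 mKO mice, and log2 fold changes (mKO minus control) are given ± SE from edgeR.

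Dmd, which encodes dystrophin and is the targeted gene, was lower in every mKO library than in every control library. It stood at 59.9, 68.2, 67.8, 66.3 and 86.8 CPM in controls 1 to 5 and at 14.5, 32.1, 24.8 and 17.4 in mKO 1 to 4. Its mean fell from 69.8 ± 10.1 to 22.2 ± 7.89 CPM, a log2 fold change of -1.65 ± 0.20 (edgeR adjusted p = 4.88e-05). These counts cover the whole gene and do not measure the deleted exon alone, and whole muscle also holds cells other than myofibers. Utrn, which encodes the dystrophin relative utrophin, stood at 25.5 ± 3.92 in controls and 22.7 ± 5.29 in mKO, with a log2 fold change of -0.17 ± 0.16 that did not pass the test (edgeR adjusted p = 0.461).

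**Figure D1:**
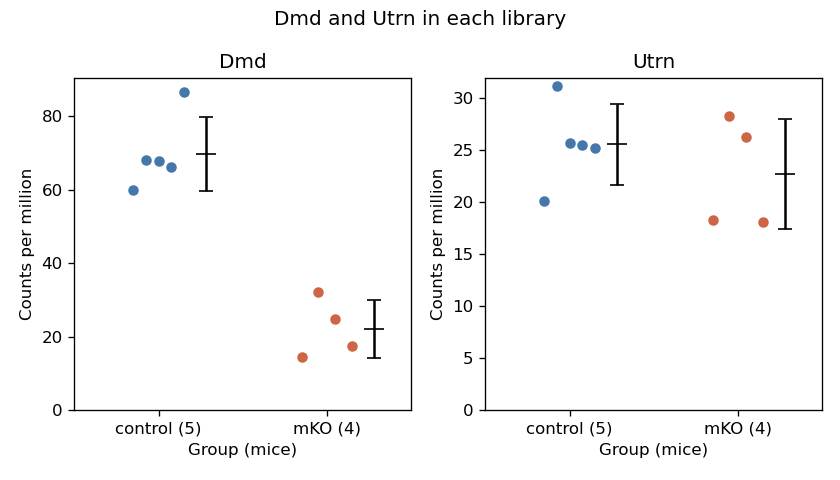
CPM of Dmd (left) and Utrn (right) in each library, 1 point per mouse, for 5 control and 4 mKO mice, with bars for mean and SD beside the points. The mKO values of Dmd lie between 14.5 and 32.1 and the control values between 59.9 and 86.8, while the groups overlap for Utrn.

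Loss of dystrophin in the myofiber went with a broad change of the muscle transcriptome. Genes of macrophages, extracellular matrix and regenerating myofibers rose, in 21 of 22, 27 of 27 and 14 of 17 members, and all 12 mitochondrially encoded genes tested fell. Of nuclear genes of oxidative phosphorylation 20 of 31 fell and of endothelial markers 8 of 12, but neither list passed camera with an estimated correlation (adjusted p = 0.254 and 0.112). Of 14403 genes tested, 4014 differed between the groups (27.9%), 2147 higher and 1867 lower in mKO. By more than 1.5-fold, 862 genes were higher and 356 lower, 1218 in all. Over all genes tested, the groups did not overlap for 3546 (24.6%), where chance gives 1.59%. The first principal component held 54.4% of the variance and separated the groups.

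The libraries also differed in composition along with the groups. Reads outside annotated genes made up 4.29%, 11.6%, 15.7%, 19.8% and 5.32% of all reads in controls 1 to 5 and 2.26% to 3.20% in mKO libraries. A single feature without a symbol (ENSMUSG00000119584) took 2.79%, 12.6%, 17.6%, 24.7% and 1.75% of gene counts in controls 1 to 5 and 0.061% to 0.119% in mKO. With controls 1 and 5 as the only controls, 1928 genes were called, 1340 higher and 588 lower, and Dmd had a log2 fold change of -1.68 (edgeR adjusted p = 0.00601). Of the 4014 genes, 1801 were called again in the same direction and none in the other. With controls 2, 3 and 4 only, 3677 genes were called, 2151 higher and 1526 lower, and Dmd was at -1.57 (edgeR adjusted p = 0.00137). No mKO library had as high a share of reads outside genes as any control, so the share and the genotype cannot be separated fully. Scaling by library size alone, which moved the median log2 fold change of all genes from -0.019 to 0.392, gave 5739 genes higher and 495 lower, a share of 92.1% higher against 53.5% with TMM.

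**Figure D2:**
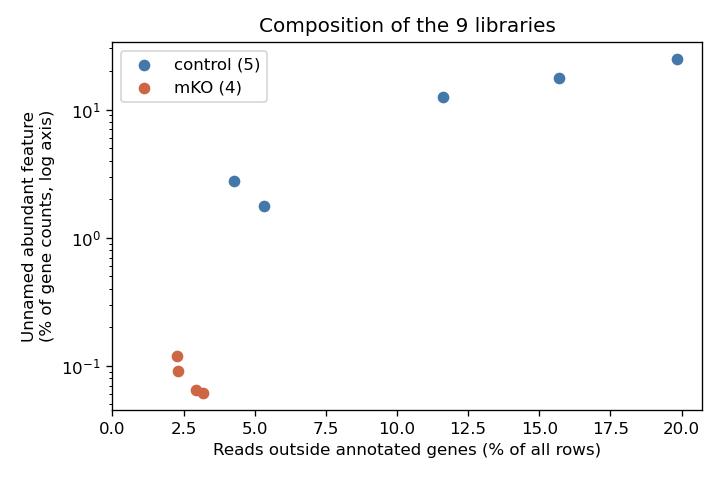
Share of reads outside annotated genes (horizontal axis, % of all reads in the table) and share of gene counts in the unnamed feature (vertical log axis, %), 1 point per library for 5 control and 4 mKO mice. The 4 mKO libraries lie at 0.061% to 0.119% on the vertical axis, and controls 2, 3 and 4 at 12.6% to 24.7%.

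The genes with the largest rises included markers of activated macrophages and of muscle cell fusion. Mmp12, a macrophage elastase, rose from 7 counts over all controls to 1635 over all mKO libraries, with a log2 fold change of 7.46 ± 0.49 (edgeR adjusted p = 2.45e-07). Cdkn2a, which encodes cell cycle inhibitors, rose by 5.95 ± 0.51, and Mymk, which encodes the fusion factor myomaker, by 5.89 ± 0.47. Serpina3n, a secreted protease inhibitor, rose from 0.673 ± 0.229 to 37.4 ± 9.39 CPM. Mmp3, Gpnmb, Trem2, Itgax, Lgals3 and Ms4a7 completed the 10 largest rises, at log2 fold changes of 5.41, 5.04, 4.96, 4.83, 4.79 and 4.73. Several of these rises start near 0 counts and their size is unsteady: without control 3 Mmp12 was at 8.23 and Cdkn2a at 6.54, and without control 4 Itgax was at 5.47. With controls 1 and 5 only, Mymk was at 10.37, Trem2 at 7.49, Lgals3 at 5.52, Itgax at 5.44 and Ms4a7 at 5.33. Of the genes named below, Ctss, H2-Eb1, Ccl6, C1qa, Cfd, Adipoq, Chrng, Angptl4, Igf2, Fos, Junb and Zfp36 also rose by more than 1.5-fold further with these controls. Several of the largest falls were in genes that varied with reads outside genes. Mir6236 (-6.52 ± 0.74), Lars2 (-6.36 ± 0.80), Lncpint (-3.91 ± 0.65) and Carmn (-3.44 ± 0.58) were each higher in controls 2, 3 and 4 than in controls 1 and 5. Without these 3 controls the falls were smaller, at -4.91 ± 0.55 for Mir6236, -3.80 ± 0.26 for Lars2 and -2.22 ± 0.50 for Lncpint, which were still called. Without control 4 alone Mir6236 was at -5.91. Without these 3 controls, Carmn moved to -2.10 ± 0.66 (edgeR adjusted p = 0.0660) and H60b from -3.59 ± 0.73 to -2.45 ± 1.06 (edgeR adjusted p = 0.169), and both were no longer called. H60b was at -4.54 without mKO 3. Ces1d, a carboxylesterase, fell from 31.6 ± 8.18 to 2.7 ± 0.452 CPM. Snph, Helt, mt-Co2 and BC049352 fell too, with log2 fold changes of -4.01, -3.97, -3.35 and -3.09, and Snph was at -4.86 without mKO 3.

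Genes of the embryonic and regenerating myofiber rose together in mKO muscle. Of 17 members tested, 14 rose, none fell and 3 were not called, with the same counts adjusted over the list alone. Myh8, the perinatal myosin heavy chain, rose from 2.47 ± 0.437 to 27.0 ± 6.24 CPM, a log2 fold change of 3.46 ± 0.18 (edgeR adjusted p = 4.00e-08). Myog, a transcription factor of myoblast differentiation, rose by 2.24 ± 0.16, and Chrna1, a subunit of the muscle acetylcholine receptor, by 1.95 ± 0.14. The list passed the camera test (adjusted p = 1.07e-26) and again with an estimated correlation (adjusted p = 0.0101). Genes of the neuromuscular junction rose in 8 of 16 members, with none lower and the same counts adjusted over the list alone (camera adjusted p = 1.46e-05, and adjusted p = 0.0133 with an estimated correlation). Ache, acetylcholinesterase, rose by 1.10 ± 0.09, Chrnb1 by 0.95 ± 0.10, and Chrng, the fetal receptor subunit, by 4.63 ± 0.50. Chrna1 and Chrng stand in both lists.

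Markers of satellite cells, the stem cells of muscle, were mixed. Of 12 members tested, 4 rose and 8 were not called, and adjusted over the list alone 4 rose and 1 fell. Vcam1 rose by 1.38 ± 0.19, Sdc4 by 0.81 ± 0.13 and Peg3 by 1.38 ± 0.25. Pax7 (0.22) and Myf5 (0.18), chosen after their values were seen, did not pass the test. The camera test did not call the list (adjusted p = 0.167). Its score was higher by 0.31 (exact permutation adjusted p = 0.0129), but the score was not called without mKO 1 (exact permutation adjusted p = 0.0516) or as a median over members (0.0929).

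Fiber type genes did not move as 1 group. Of 11 slow fiber members 6 rose, 3 fell and 2 were not called, and adjusted over the list alone 8 rose and 3 fell. Tnni1, the slow troponin I, rose by 2.73 ± 0.24 and Atp2a2, the slow calcium pump, by 1.52 ± 0.16. Myh7b fell by 1.45 on the log2 scale and Myl3, a slow myosin light chain, fell by 1.87. Myh7, the slow myosin heavy chain, chosen after its values were seen, rose by 3.14. The list passed the camera test narrowly (adjusted p = 0.0418), but not with an estimated correlation (adjusted p = 0.497) nor without control 1 (0.0629), control 5 (0.0867), mKO 1 (0.101) or mKO 3 (0.167). It was also lost with controls 2, 3 and 4 only (0.195), without controls 1 and 2 (0.0809), with fry (0.0760), by library size alone (0.0805) and with a filter of 1 CPM in 4 libraries (0.0513). Of 12 fast fiber members 1 rose and 11 were not called (camera adjusted p = 0.526).

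Macrophage genes showed a strong rise. Of 22 macrophage and monocyte markers 21 rose and 1 was not called, and adjusted over the list alone all 22 rose. Ctss, a lysosomal protease of antigen-presenting cells, rose from 1.22 ± 0.401 to 31.8 ± 8.69 CPM, a log2 fold change of 4.69 ± 0.24 (edgeR adjusted p = 4.00e-08). Lyz2, lysozyme, rose by 3.49 ± 0.22 and Gpnmb by 5.04 ± 0.30. The list passed camera (adjusted p = 2.51e-53, and adjusted p = 0.0133 with an estimated correlation). Complement genes rose in 14 of 15 members, with the same count adjusted over the list alone (camera adjusted p = 3.57e-18, and adjusted p = 0.0271 with an estimated correlation). C1qa, C1qb and C1qc, subunits of the initiating complex made by macrophages, rose by 2.74, 2.84 and 2.56, and Cfd, complement factor D, by 3.61. Of 12 chemokine and cytokine genes 8 rose and 1 fell, and adjusted over the list alone 10 rose and 1 fell (camera adjusted p = 1.43e-09, and adjusted p = 0.0399 with an estimated correlation). Ccl6, Ccl7 and Ccl9 rose by 3.32, 3.96 and 2.95, and Tgfb1 by 1.24.

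Genes of antigen presentation rose in 7 of 14 members, with the same count adjusted over the list alone. The members with the smallest adjusted p were Cd74, H2-Aa, H2-Ab1 and H2-Eb1 of the class II pathway, at log2 fold changes of 1.62, 1.44, 1.25 and 1.55. Camera called the list (adjusted p = 5.20e-04), but not with an estimated correlation (adjusted p = 0.284). Among neutrophil and mast cell markers 3 of 8 rose, with the same count adjusted over the list alone. Tpsb2 and Mcpt4, mast cell proteases, rose by 1.52 ± 0.32 and 1.41 ± 0.32, while Cma1, another one, did not pass the test (0.47 ± 0.40, edgeR adjusted p = 0.42). That list missed the camera threshold (adjusted p = 0.124), while its score was higher by 0.65 (exact permutation adjusted p = 0.0129). Of T and NK cell markers 2 of 17 passed the filter and of keratinocyte markers 2 of 7, too few for a list test. In each of these lists 1 of the 2 rose, also adjusted over the list alone.

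Genes of the extracellular matrix rose without exception among the members tested. All 27 were called higher, also adjusted over the list alone. Col3a1 and Col1a2, fibrillar collagens, rose from 65.4 ± 8.17 to 373 ± 45.3 and from 65.1 ± 7.68 to 343 ± 68.7 CPM. Col5a2 rose by 2.02 ± 0.12 and Bgn, biglycan, by 2.10 ± 0.13. The list passed camera (adjusted p = 5.46e-54, and adjusted p = 0.00243 with an estimated correlation). Markers of fibroblasts and fibro-adipogenic progenitors rose in 10 of 15 members, and in 12 adjusted over the list alone (camera adjusted p = 2.39e-07, but adjusted p = 0.141 with an estimated correlation). Lox, a collagen cross-linking enzyme, rose by 2.55 ± 0.29 and Lum, lumican, by 1.51 ± 0.17. Tendon markers rose in 7 of 8 members, and in 8 adjusted over the list alone (camera adjusted p = 7.87e-11, and adjusted p = 0.0399 with an estimated correlation). Thbs4 rose by 1.61 ± 0.09, Comp by 3.20 ± 0.29 and Fmod by 2.78 ± 0.34. Of 9 adipocyte markers 5 rose and 4 were not called, and adjusted over the list alone 5 rose and 1 fell (camera adjusted p = 0.0138, but adjusted p = 0.221 with an estimated correlation). Adipoq, adiponectin, rose from 0.494 ± 0.547 to 3.70 ± 0.683 CPM, and without control 2 the control mean was 0.264. Without control 2 Cfd was at 4.20. Cfd stands in the adipocyte and complement lists.

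Genes of the dystrophin-associated complex changed in both directions. Of 16 members 7 rose and 1 fell, with the same counts adjusted over the list alone. Sntb1, a syntrophin, rose by 1.59 ± 0.23, Lama2, a laminin chain of the muscle basement membrane, by 1.16 ± 0.17, Cav3 by 0.69 ± 0.12 and Sspn, sarcospan, by 0.63 ± 0.11. The member that fell was Nos1 (-0.52), chosen after its values were seen. Camera called the list (adjusted p = 0.0227), but not with an estimated correlation (adjusted p = 0.104) nor with controls 1 and 5 only (adjusted p = 0.0649). The estimated correlation was -0.01, below the preset 0.01, so a higher correlation between members does not account for the first of these losses. Membrane repair genes rose in 13 of 17 members, and in 14 adjusted over the list alone (camera adjusted p = 8.74e-10, and adjusted p = 0.0133 with an estimated correlation). The annexin genes Anxa1, Anxa2, Anxa4 and Anxa7 rose by 2.31, 1.90, 2.05 and 1.10, beside the rise of macrophage and matrix markers in the same libraries. Of 20 costamere and integrin genes 8 rose and 2 fell, and adjusted over the list alone 8 rose and 3 fell. Ankrd1 rose by 2.79 ± 0.25, and the integrin genes Itga7, Itga5 and Itgb1 by 0.80, 0.79 and 0.69. The costamere call (camera adjusted p = 0.0418) was lost with an estimated correlation (adjusted p = 0.475), with controls 2, 3 and 4 only (0.0546), and without control 5 (0.0605), mKO 2 (0.0699) or mKO 3 (0.125), as well as with a filter of 1 CPM in 4 libraries (0.0513).

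Genes of the mitochondrial genome were lower in mKO muscle, and nuclear genes of oxidative phosphorylation were lower with TMM scaling. All 12 mitochondrial protein genes tested fell, also adjusted over the list alone (camera adjusted p = 2.39e-22, and adjusted p = 0.0187 with an estimated correlation). mt-Nd4, a subunit of complex I, fell from 16720 ± 1150 to 6809 ± 1308 CPM, a log2 fold change of -1.30 ± 0.14 (edgeR adjusted p = 2.15e-05). Mitochondrial genes took 15.7% ± 2.96 of gene counts in controls and 10.01% ± 1.57 in mKO. mt-Co2, mt-Co3 and mt-Atp6 had log2 fold changes of -3.35, -2.90 and -2.17, but 5 of the 12 genes, these included, have a near-identical nuclear copy, and their counts are uncertain. The 7 others had log2 fold changes from -1.30 to -0.70. Of these, mt-Nd4 has a copy of 100% identity over 63.6% of its length. mt-Co1, chosen after its values were seen, has one of 97.6% identity over its whole length. Part of the reads of these 2 genes may be uncertain too. Of 31 nuclear genes of oxidative phosphorylation 20 fell and 11 were not called, and adjusted over the list alone 22 fell. Ndufs8 fell from 190 ± 20.9 to 108 ± 8.96 CPM, and Uqcrc1 from 1031 ± 78.1 to 644 ± 58.1. Ndufa4 and Cox6c fell by 0.78 and 0.69 on the log2 scale. Camera called the nuclear list (adjusted p = 3.31e-08), but not with an estimated correlation (adjusted p = 0.254). Its score was lower by 0.48 with TMM, and by library size alone the difference was -0.06, while camera with the preset correlation still called the list lower. By library size alone Uqcrc1, Ndufa4 and Cox6c moved to -0.27, -0.36 and -0.28 and were not called (edgeR adjusted p = 0.135, 0.0512 and 0.116).

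**Figure D3:**
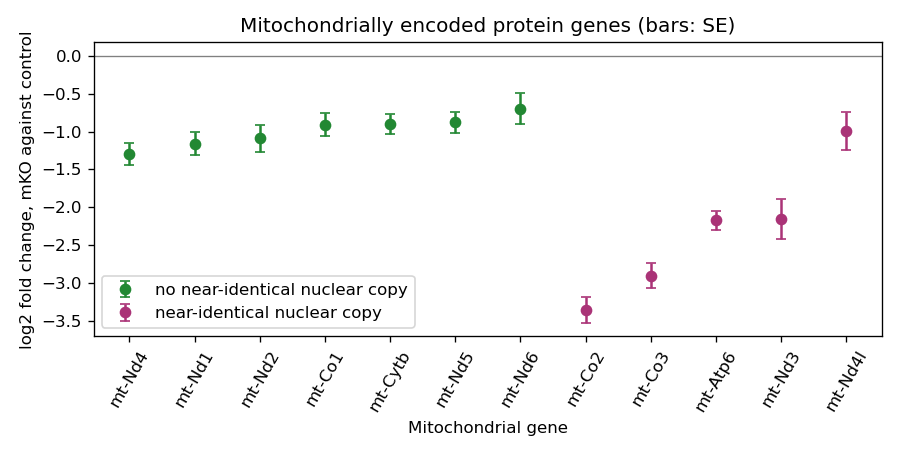
Log2 fold change (vertical axis, mKO against control, bars for SE) of the 12 mitochondrially encoded protein genes tested, from 5 control and 4 mKO mice, coloured by whether a near-identical nuclear copy exists. The 7 genes without such a copy lie between -1.30 and -0.70, and the 5 with one between -3.35 and -0.99.

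Genes of fatty acid uptake and oxidation fell in 12 of 23 members, with 1 higher and 10 not called, and adjusted over the list alone 13 fell and 1 rose. Mlycd, Acaa2 and Cpt1b, the muscle carnitine palmitoyltransferase, fell by 0.66, 0.51 and 1.68 on the log2 scale, while Angptl4, a secreted inhibitor of lipoprotein lipase, rose by 2.72 ± 0.36. The groups overlapped for Cpt1b, at 10.2 CPM in control 1 but 1.44 in control 5, below every mKO library (1.49 to 2.24). With controls 1 and 5 only, Cpt1b was no longer called (-1.58 ± 0.54 against -1.68 ± 0.37, edgeR adjusted p = 0.0889), and of these controls only control 1 carries the fall. Controls 2, 3 and 4 stood at 5.80, 6.47 and 6.57 CPM, above every mKO library. By library size alone Mlycd and Acaa2 moved to -0.24 and -0.11 and were not called (edgeR adjusted p = 0.182 and 0.556). Camera called the list (adjusted p = 0.00721), but not with an estimated correlation (adjusted p = 0.254). By library size alone its score difference turned from -0.23 to 0.188 (exact permutation adjusted p = 0.0844), while camera with the preset correlation still called the list lower. Endothelial markers fell in 8 of 12 members, with none higher, and in 11 adjusted over the list alone. Kdr and Flt1, receptors of vascular endothelial growth factor, fell from 59.2 ± 10.4 to 28.6 ± 6.40 and from 73.7 ± 13.1 to 41.2 ± 4.45 CPM. Ptprb fell by 0.82 and Tie1 by 0.77 on the log2 scale, and Tie1 was not called with controls 1 and 5 only (-0.63 ± 0.19 against -0.77 ± 0.15, edgeR adjusted p = 0.0625) or by library size alone (-0.34 ± 0.16, edgeR adjusted p = 0.0880). Camera called the endothelial list (adjusted p = 9.50e-05), but not with an estimated correlation (adjusted p = 0.112). Its score difference of -0.63 became -0.213 by library size alone (exact permutation adjusted p = 0.195), while camera with the preset correlation still called the list lower. None of 9 pericyte and smooth muscle markers was called (camera adjusted p = 0.526), and none was at an adjusted p under 0.05 over the list alone.

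**Figure D4:**
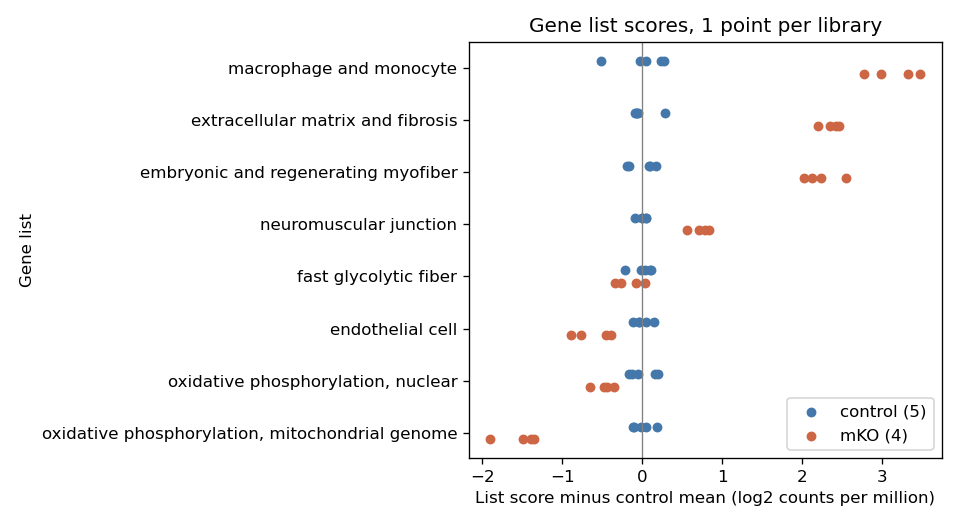
Scores of 8 gene lists (mean log2 CPM of the members) minus the control mean, 1 point per library for 5 control and 4 mKO mice. Macrophage, matrix and regenerating myofiber scores were higher in all 4 mKO libraries than in every control library, with mean differences of 3.14, 2.36 and 2.23, and the fast fiber scores of the groups overlap. By library size alone the fast fiber difference turned from -0.16 to 0.251.

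Genes of stress and protein folding rose in part. Of 19 genes of the unfolded protein response 12 rose and 2 fell, and adjusted over the list alone 13 rose and 2 fell (camera adjusted p = 9.50e-05, but adjusted p = 0.154 with an estimated correlation). Hspa5, the chaperone BiP, rose from 122 ± 7.03 to 207 ± 28.4 CPM, and the disulfide isomerase genes Pdia3, Pdia4 and Pdia6 rose by 0.82, 1.12 and 0.93. Of 18 oxidative stress genes 9 rose and 2 fell, and adjusted over the list alone 10 rose and 3 fell (camera adjusted p = 1.42e-04, and adjusted p = 0.0187 with an estimated correlation). Hmox1, heme oxygenase, rose by 1.57 ± 0.14 and Mt1, a metallothionein, by 2.77 ± 0.28. Cyba and Cybb, which rose by 1.69 and 3.18, encode the phagocyte NADPH oxidase, and macrophage markers rose in the same libraries. Of 19 autophagy and lysosome genes 9 rose and 1 fell, and adjusted over the list alone 9 rose and 2 fell (camera adjusted p = 0.00338, but adjusted p = 0.154 with an estimated correlation). The cathepsin genes Ctsk, Ctsb and Ctsl rose by 2.27, 0.64 and 0.55 beside the same rise of macrophage markers. Of 15 heat shock genes 9 rose and 1 fell, with the same counts adjusted over the list alone. Hspb7 and Dnajb1 rose by 0.75 and 0.98, Hspa1b, whose counts are uncertain because of a near-identical copy, rose by 1.59, and Hspa1l fell by 1.12 on the log2 scale. With controls 1 and 5 only, Hspb7 was not called (0.60 ± 0.19 against 0.75 ± 0.15, edgeR adjusted p = 0.0755). The heat shock call (camera adjusted p = 0.0488) was lost with an estimated correlation (adjusted p = 0.497), with controls 1 and 5 only (0.0874), and without control 2 (0.122), control 5 (0.0545), mKO 2 (0.0565) or mKO 4 (0.121). It was also lost without controls 1 and 2 (0.0984) and with a filter of 1 CPM in 4 libraries (0.0574).

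Cell cycle genes rose from very low levels. Of 18 members 14 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.09e-07, but adjusted p = 0.166 with an estimated correlation). Mki67, a marker of dividing cells, rose from 0.266 ± 0.0817 to 3.86 ± 1.67 CPM, and Rrm2 and Top2a rose by 3.60 and 4.38 (Top2a by 4.98 without control 3). Of 21 genes of TGF-beta and myostatin signalling 7 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0075, but adjusted p = 0.0743 with an estimated correlation). That estimate was 0.007, below the preset 0.01, so a higher correlation between members does not account for the lost call. Fstl1 rose by 1.60 ± 0.14, and Mstn, which encodes the muscle growth inhibitor myostatin, fell from 26.2 ± 5.56 to 11.4 ± 1.27 CPM. Of 17 polyamine and growth genes 7 rose and 1 fell, and adjusted over the list alone 9 rose and 3 fell. Runx1 rose by 3.21 ± 0.20 and Igf2 by 2.48 ± 0.44, and Amd1, an enzyme of polyamine synthesis with a near-identical copy, fell by 0.88 on the log2 scale. The polyamine and growth call (camera adjusted p = 0.0352) was lost with an estimated correlation (adjusted p = 0.154), with controls 1 and 5 only (0.0686), with controls 2, 3 and 4 only (0.0546), without control 2 (0.0667) and without controls 1 and 2 (0.0984). Amd1 was not called by library size alone (-0.49 ± 0.20 against -0.88 ± 0.17, edgeR adjusted p = 0.0598). Immediate early genes rose in 10 of 18 members, and in 11 adjusted over the list alone (camera adjusted p = 8.92e-05, but adjusted p = 0.254 with an estimated correlation). Fos rose from 6.31 ± 3.69 to 65.3 ± 47.2 CPM, and Junb, Atf3 and Zfp36 rose by 3.43, 1.96 and 1.36. Single libraries carry part of this: without mKO 1 the mKO mean of Fos was 42.3 CPM, and without mKO 3 that of Junb was 65.7 CPM against 123 with it, a log2 fold change of 2.55. The score of this list was higher by 1.26 (exact permutation adjusted p = 0.0332), and without mKO 1 its exact permutation adjusted p was 0.0516.

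Of the 39 lists tested, camera called 22 higher and 4 lower in mKO, and 10 of these 26 also passed with an estimated correlation. With controls 1 and 5 only 25 lists passed camera, and with controls 2, 3 and 4 only 24 did. The list scores of 28 lists differed between the groups by the exact permutation test, 25 of them among the 26.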

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

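The tests of nuclear copies, of silent genes, of fast fiber scores and of transcript length were chosen only after the results they bear on had been seen. The counts over other splits, the comparison among controls and the scalings were set before.

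In each group, the library farthest from the others was compared with the group's whole range by Dixon's criterion. Of 346 groups of values 14 passed, where chance alone gives about 1 in 20, or 17.3. CPM values stood apart for Mir6236 in mKO 4 (5.48, ratio of gap to range 0.858), Chrna1 in control 4 (8.76, 0.753), Vcam1 in mKO 3 (3.96, 0.840), Itga7 in mKO 1 (134, 0.876), Acaa2 in control 3 (151, 0.744), Hspa1b in control 3 (3.66, 0.777) and Cyba in control 1 (3.04, 0.739). mt-Co3 stood apart in control 5 (198, 0.805) and in mKO 1 (25.1, 0.873). List scores stood apart for satellite cells in mKO 1 (3.15, 0.834), extracellular matrix in control 2 (2.96, 0.903), the unfolded protein response in control 4 (4.53, 0.746) and oxidative stress in control 1 (3.94, 0.802). Reads that matched more than 1 place made up 15.6% of reads in control 5 (0.779) and at most 12.8% in the other controls.

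The number of genes called was set against other splits of the 9 libraries into 5 and 4, of which 100 were drawn, the real one included. For 4014 genes called, 1 of 100 splits, the real one, gave as many, and the highest other split gave 537. For 1218 genes changed by more than 1.5-fold, 1 of 100 gave as many, and the highest other gave 12. This argues against chance for both counts, although 100 splits allow no share below 1 in 100. For 26 lists past camera, 3 of 100 splits gave as many, and the highest other gave 27, with 3 of the 4 mKO libraries kept together and 0 genes called. This is under the limit of 5 in 100 set before, but a split without any gene called gave more lists, so the number of lists alone does not set the real split apart. Splits with 2 mKO libraries in the group of 4 are nearly balanced and called 0 genes. Camera with the preset correlation still called 1 to 14 lists in them, so a list call with that setting alone is weak evidence.

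Controls 2, 3 and 4 held more reads outside annotated genes and more of the unnamed feature than controls 1 and 5, and mKO libraries held the least. If this difference were the whole cause of the called genes, controls 1 and 5 could be expected to lie towards mKO, but 47.8% of the called genes moved that way, and the highest of the 10 ways to part the controls gave 59.3%. Control 5 also stood apart on the second principal component, at -54.3 against 8.94 to 27.7 in the other controls. Its own deviation may therefore blur this comparison. Genomic DNA was argued against, since the change of silent receptor genes was -0.382% of the rise that the reads outside genes predict. A carry-over of ribosomal RNA is a candidate explanation that no sequence at hand could test, and the large falls of Mir6236 and Lars2 go with it. A difference in library preparation that follows the groups cannot be told apart from genotype, because all mKO libraries lie on 1 side.

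Mitochondrial genes with a near-identical nuclear copy fell more than the others, by a median log2 fold change of -2.17 against -0.91, a difference of -1.26 (exact permutation p = 0.0126 over 12 genes, which are not independent). Reads shared with a nuclear copy may therefore account for the larger falls. Genes with a copy had group means of at most 214.7 CPM and the others of at least 1971 CPM, so copy and level cannot be told apart. Shared reads as the whole cause are argued against, since all 7 genes without such a copy were called lower. Some of the 7, mt-Nd4 among them, have a partial or less similar copy. mt-Nd1, chosen after its values were seen, had no match in the search and a log2 fold change of -1.16 (edgeR adjusted p = 9.50e-05). What remains open is a difference in library preparation, as above, loss of dystrophin, and anything else that came with the mKO genotype. The design does not separate these.

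Nuclear genes of oxidative phosphorylation fell in 20 of 31 members. Loss of dystrophin, anything else that came with the mKO genotype and a preparation difference between the groups stay open as causes. So does the scaling for the size of the fall. A lower share of myofiber RNA is argued against, since the score of these genes minus that of fast fiber genes was lower in mKO by -0.317 (exact permutation p = 0.0397), although mKO 1 lay within the range of the controls. A scaling factor per library cancels in this difference, so the scaling does not account for the fall relative to fast fiber genes. Transcript length as the whole cause is argued against, since the median log2 fold change of the list was -0.43, a difference of -0.285 from lists matched on length and expression. The length used was that of the longest annotated transcript of a gene, which need not be the one expressed, so the matching is rough. The matched lists also fell, at a median of -0.15, so length or expression may go with part of the fall. With DESeq2 size factors and upper-quartile scaling the score difference was -0.459 or below, which meets the bound set before, but these moved the median of all genes from -0.02 only to -0.01 and 0.01 and so do not test the scaling (a shift of 0.1 was asked for after these values were seen). By library size alone, where that median was 0.40, the difference was -0.06 (exact permutation adjusted p = 0.652), and with the unnamed feature and Lars2 also left out it was -0.264 (exact permutation adjusted p = 0.0221). Camera with the preset correlation, which sets the list against all other genes, still called it lower by library size alone.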

How the results depend on the processing

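The alternatives that leave out controls 2, 3 and 4, keep only these, or leave out the abundant unnamed feature with Lars2 were chosen after seeing the data. Dmd stayed lower and called in all alternatives, and without each library in turn its log2 fold change ran from -1.86 to -1.48. Leaving out each library in turn gave 3168 to 4255 genes called, 1769 to 2331 higher, 1399 to 1924 lower, 1015 to 1238 beyond 1.5-fold, 23 to 28 lists past camera and 25 to 29 list scores. By library size alone 6234 genes were called, 5739 higher and 495 lower, and 1887 beyond 1.5-fold, and 2642 of the 4014 genes were called again in the same direction. Library size alone with the unnamed feature and Lars2 left out gave 3885 higher and 895 lower. Without controls 1 and 2, 1205 genes were lower. Without controls 2, 3 and 4, 1928 genes were called, 1340 higher and 588 lower, with 790 beyond 1.5-fold, and 0 list scores passed, because 2 against 4 libraries allow no p below 0.0667 (camera called 25 lists). The other 9 pairs of controls gave 1743 to 3042 genes, so fewer libraries may account for the lower total. Of the genes 69.5% were higher, against 59.5% to 66.8% in the other pairs, and the 3 other pairs with control 5 came near, with 64.9% to 66.8% higher and 600 to 674 genes lower. With an estimated inter-gene correlation 10 lists passed camera. None of the 4014 genes was called in the opposite direction under any alternative. By library size alone the score differences of fast fiber (0.251), fatty acid (0.188), atrophy (0.310) and circadian clock genes (0.0265) turned higher, and the circadian difference was 0.0629 as a median over members. The cause of these turns was not tested beyond the shift of the median of all genes. Of the values of genes taken by the naming rule, Dmd aside, 2994 kept their side of the threshold under the alternatives, 22 lost the call and 1 gained it. No called direction was reversed, but a change of direction in a gene called in neither fit was counted among the 2994. Most of these genes were picked for a small adjusted p or a large change, so these counts do not describe the 4014 genes. In the simulation, 1.5-fold changes were mostly missed (35.3% of 68 were called). A smaller share of genes was changed there than was called here, which makes the adjusted threshold stricter, so that figure may be too low for these data.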

Other observations

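Genes of this part outside the rule for named genes were chosen after their values were seen. Clock-controlled genes were lower in part: of 17 core circadian genes 5 fell and 1 rose, and adjusted over the list alone 5 fell and 2 rose. Dbp and Hlf, output regulators of the clock, fell from 80.4 to 36.7 and from 15.5 to 4.84 CPM, Ciart fell by 2.14 on the log2 scale, and Nfil3 rose by 0.98. The score of the list was lower by 0.39 (exact permutation adjusted p = 0.0229), but not past the threshold without control 2, 3, 4 or 5 or mKO 1 (exact permutation adjusted p from 0.0696 to 0.0796). The time of day of tissue collection is not given in the sources used here. Camera did not call it (adjusted p = 0.0556), but did without control 1 (0.0331), control 2 (0.0496), control 3 (0.0472) or mKO 3 (0.0310). Of 17 genes of the tricarboxylic acid cycle 7 fell and 1 rose, and adjusted over the list alone 8 fell and 1 rose (camera adjusted p = 0.0556, and 0.0319 without control 2, 0.0410 without control 3, 0.0386 without control 4 and 0.0285 without mKO 4). Of 10 Schwann cell markers 3 fell, and adjusted over the list alone 6 fell and 1 rose (camera adjusted p = 0.0556, and 0.0263 without control 1, 0.0348 without control 4, 0.00756 without mKO 1 and 0.0437 without mKO 3).

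Other lists showed single members that moved. Of 21 calcium handling genes 5 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.899). Sln, the calcium pump inhibitor sarcolipin, rose by 1.48 and Mrln, the related inhibitor myoregulin, fell by 1.55 on the log2 scale. Of 17 atrophy genes 1 rose and 4 fell, and adjusted over the list alone 1 rose and 5 fell (camera adjusted p = 0.185). Fbxo32, the ubiquitin ligase atrogin-1, fell by 0.62 on the log2 scale, and Gadd45a rose by 1.45. Of 20 genes of glycolysis and glycogen 2 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.582). Of 18 interferon genes 1 rose, also adjusted over the list alone (camera adjusted p = 0.582). Of 5 red blood cell genes 2 rose, and 3 adjusted over the list alone (camera adjusted p = 0.0755, and 0.0393 without control 2 and 4.26e-04 without mKO 1). Of 4 B and plasma cell genes 1 rose, also adjusted over the list alone (camera adjusted p = 0.582).

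The median of the longest 20% of transcripts minus that of the shortest 20% ran from -0.29 to 0.37 on the log2 scale in mKO libraries and from -0.22 to 0.23 in controls, each relative to the mean over libraries, so libraries of both groups differ in both directions.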
